A study of Mus musculus with 15 samples.

How the data were processed

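RNA from 12 mouse liver tumours and 3 normal livers was purified on columns with DNase treatment, enriched for poly-A RNA and made into libraries with a TruSeq RNA kit, per the labels' protocols. The deposited table holds raw read counts per gene symbol for 15 libraries and 23284 symbols, not normalized by the authors. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1.0, Bowtie2 2.2.4 and HTSeq 0.6.1 were used with the mouse build mm9. Their settings, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Without strand, reads of overlapping antisense genes cannot be told apart. Genes with near-identical copies, such as the Mup, Cyp2a, Cyp2c, Cyp4a, Ugt2b and Sult2a families, are uncertain, because reads with several matches may have been dropped or split. Gapdh, which has many processed copies in the mouse genome, was at 4.90 CPM in normal liver and 11.9 CPM in floxed tumours, and Hmgb1, which has such copies too, may be under-counted in all groups alike. The reference in hand was of another build (GRCm38.p6), so it served only for gene names and for which genes neighbour each other, and no coordinates are given.

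Groups came from the sample labels. The deposited counts were analysed as given in R 4.3.3. For each pair of groups, genes were kept with edgeR 4.0.16's filterByExpr, libraries were scaled with TMM factors, and the quasi-likelihood F test was fitted with robust dispersions to the 2 groups compared, with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no fold threshold. CPM values are counts scaled to a common library total by TMM over all 15 libraries, given as mean ± SD. Standard errors of log2 fold changes come from the F statistic. The precision of a CPM value follows from 18973246 to 30929442 counts per library, and floors and counting intervals (95%) cover counting error only. A fold against a group with 0 counts was computed against 3 counts over the group. The lowest chi-square per degree of freedom between libraries of a group was 27.9, so no library was counted as a repeat of another.

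Before the data were examined, 35 gene lists with 619 entries were fixed, and 615 entries were matched in the table, 6 of them by an older symbol and 2 by a synonym. Lists with at least 4 tested members were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move one way and does not compare them with other genes, were run beside it. Hmgb1 was tested with an exact two-sided permutation test of log2(CPM + 1). Genes named in the text are Hmgb1, the 5 largest rises and 5 largest falls per comparison among called genes with a mean log CPM of at least 1, and from each list up to 2 members with the smallest p, or up to 4 in the 8 lists with the smallest camera p. Some list members under this rule are left out where the list's count is given. Mup3, Cyp7b1, Oat, Ccng1 and Trib3 are left out for Hmgb1-deleted against floxed tumours because of their values, after their calls were seen to end when single libraries were left out. Separately, 1 other gene is left out of the text and of the search for libraries that stand apart, for a reason that does not rest on its values. Cyp2a4 in single libraries, H2-Ea-ps in single libraries and the genes of the closing observations that the rule does not give were chosen after their values were seen.

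On simulated counts with 200 genes changed, edgeR recovered 54% of genes changed 2-fold and 91% of genes changed 4-fold for Hmgb1-deleted against floxed tumours (13356 genes). It recovered 32% and 87% for floxed tumours against normal liver (13662 genes) and 31% and 81% for Hmgb1-deleted tumours against normal liver (13632 genes). False calls were 2.01%, 3.23% and 9.38% of edgeR's calls in these simulations, and 16%, 18.97% and 28.4% of those of DESeq2 1.42.0. A list raised 2-fold as a whole was called in each simulation and no other list was. The simulated genes were drawn independently, so false list calls from correlated members could not show there.

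The alternatives tried were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM, DESeq2, voom with sample weights, all 15 samples in 1 fit, the shared replicate number as a block, and each library left out in turn. For lists they were the estimated correlation, fry, RLE, the joint fit, the block and left-out libraries. For Hmgb1 they were a pseudocount of 0.1 and library totals without a factor, and for the overlap an adjusted p under 0.01 and RLE. Library totals without a factor for the gene counts, leaving out Hmgb1-deleted tumours 2 and 5, 3 and 4, or 3, 4 and 6, and a fit of numbers 1 to 3 without the block were chosen after seeing the data. The removal of 3, 4 and 6, the tumours nearest to normal liver, selects libraries by their outcome, so its counts are no estimate of the effect.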

Results

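Liver RNA from 15 mouse samples was sequenced to ask how loss of Hmgb1 in the liver bears on the expression programme of chemically induced liver tumours. Hmgb1 encodes a chromatin protein that also acts as an alarm signal when dying cells release it. There were 6 tumours from floxed control mice, in which Hmgb1 is intact, 6 tumours from mice in which Albumin-Cre deletes Hmgb1 in liver epithelium, and 3 normal livers of the C57BL/6 strain with no treatment named. Tumours were induced with the mutagen diethylnitrosamine at 25 mg/kg on day 15 after birth and with the liver toxin carbon tetrachloride at 0.5 µl/g weekly from week 8 for 15 weeks. Total counts were 20191452 to 30929442 in floxed tumours, 18973246 to 26293378 in Hmgb1-deleted tumours and 23193714 to 26997782 in normal livers. Counting error allowed up to 0.11 to 0.169 CPM (counts scaled to a common library total) for a gene with 0 counts in a library. The labels give no litter or batch and do not say whether any tumours came from the same mouse, so p-values measure the spread between these samples. No treated liver without tumour was among the samples, so tumours and normal livers differ in treatment as well as in being tumour. The strain of the floxed and Hmgb1-deleted mice is not given in the labels, so strain may differ too between tumours and the C57BL/6 livers, and among the tumours.

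Hmgb1 itself was measured first. Its level was 27.9 CPM ± 3.36 (SD, n = 6) in floxed tumours, 14.8 CPM ± 2.76 (SD, n = 6) in Hmgb1-deleted tumours and 23.9 CPM ± 6.07 (SD, n = 3) in normal livers. Every Hmgb1-deleted tumour lay below every floxed tumour, and the mean was 52.8% of the floxed level (exact permutation test, two-sided, p = 0.00216, the smallest it can give, adjusted p = 0.00649 over 3 pairs of groups). Against normal liver, Hmgb1-deleted tumours were lower (exact permutation p = 0.0238, the smallest possible, adjusted p = 0.0357), and floxed tumours did not differ detectably (exact permutation p = 0.167). The 2 comparisons with normal liver gave log2 differences of -0.65 and 0.24. On library totals without a scaling factor the lower level against normal liver missed the threshold at a difference of -0.38 (exact permutation p = 0.19), and with 2 normal livers an exact permutation p cannot go below 0.0714. The deletion acts in hepatocytes and bile duct cells, other liver cells keep the gene, and the labels do not say which exons were removed.

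**Figure D1:**
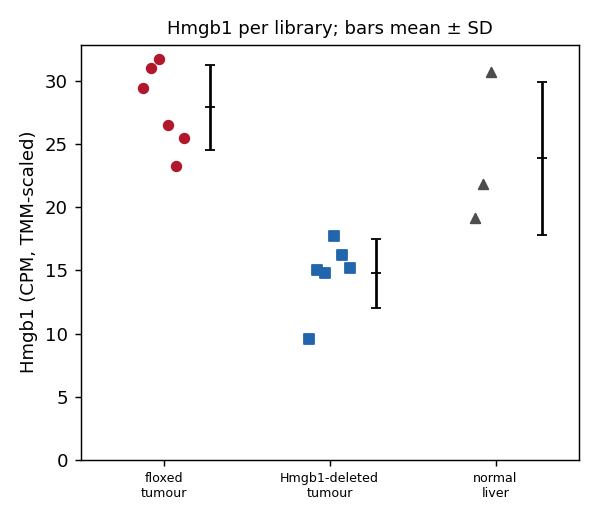
Hmgb1 in CPM for each of the 15 libraries by group (points), with the group mean ± SD (bars); the axis starts at 0. The 6 Hmgb1-deleted tumours lie between 9.59 and 17.8 CPM and the 6 floxed tumours between 23.3 and 31.8 CPM.

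Over all genes the normal livers stood together and apart from the tumours. The first principal component of log2 CPM held 46.9% of the variance, with normal livers at 108.9 to 109.3, floxed tumours at -61.6 to -42.9 and Hmgb1-deleted tumours at -28.5 to 26.4. Hmgb1-deleted tumours 3, 4 and 6 lay nearest to normal liver, at 20.9, 26.4 and 9.38. Hmgb1-deleted tumours 2 and 5 stood apart on the second component (15.98% of the variance) at -76.1 and -82.5, and Cyp2a4, a steroid hydroxylase, was at 11.2 and 21.5 CPM there against 2517 to 3604 CPM in the other 4. Albumin mRNA took 11.2% to 19.6% of counts in floxed tumours, 7.69% to 12.997% in Hmgb1-deleted tumours and 7.66% to 9.37% in normal livers.

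**Figure D2:**
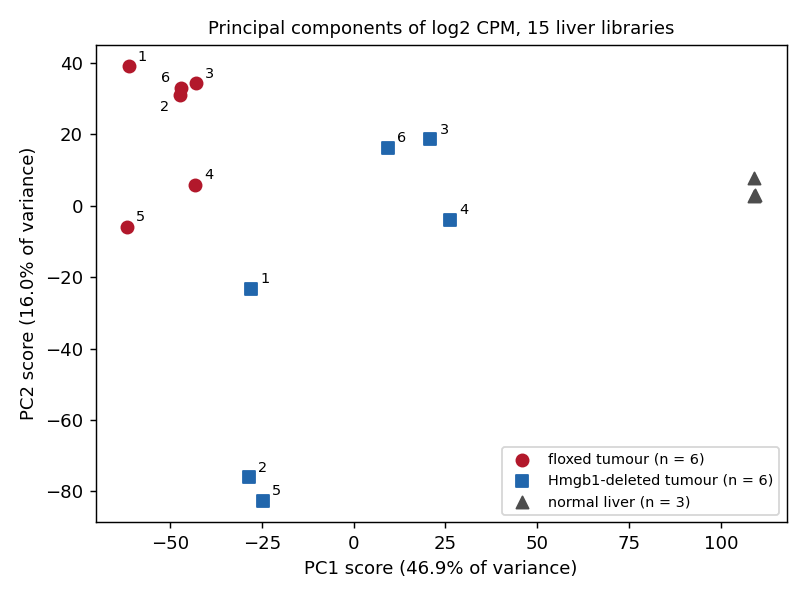
Scores of the 15 libraries on the first (x axis) and second (y axis) principal component of log2 CPM, in score units; colours and markers show the group, and numbers name the tumours of each group. Normal livers lie near 109 on the first component, and Hmgb1-deleted tumours 3, 4 and 6 lie between them and the floxed tumours.

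The comparison of Hmgb1-deleted with floxed tumours asks how the tumour transcriptome differs with the deletion. The labels do not say whether the 2 groups are matched in strain or litter. Against floxed tumours, Hmgb1-deleted tumours had less RNA of the fetal and oncofetal liver list. They had more RNA of the bile acid, cytochrome P450 and fatty acid oxidation lists. The fetal list kept its call with an estimated correlation, and the other 3 lost it (adjusted p = 0.221, 0.807 and 0.324 with an estimated correlation). Ly6d, a surface protein, was at 41.0 CPM ± 27.4 (SD, n = 6) against 389 CPM ± 126 (SD, n = 6), and H19, an imprinted RNA of fetal liver, at 3.96 CPM ± 7.07 against 89.8 CPM ± 79.7. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 52.2 CPM ± 14.4 against 6.65 CPM ± 3.16. In all, 1045 of 13433 tested genes changed, 598 higher and 447 lower, and 529 of them by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The balance of higher and lower genes depended on the scaling. It was near even with RLE factors (535 higher and 524 lower) and with upper-quartile factors (561 and 560). The split was 982 higher and 257 lower on library totals without a factor, a scaling tried after seeing the data.

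The fetal and oncofetal liver list fell as a group. It mixes genes of fetal liver, such as H19 and Afp, with genes that are not particular to fetal liver, such as Cd63, so its fall is not that of fetal genes alone. Of 17 tested members 5 were lower (6 adjusted over the list alone) and the other 12 did not pass. The list's median log2 fold change was -1.40 (camera adjusted p = 6.64e-05; adjusted p = 0.025 with an estimated correlation). Ly6d had a log2 fold change of -3.22 ± 0.47 (SE, adjusted p = 0.00405), H19 of -4.46 ± 0.99 (adjusted p = 0.0186), Scd2, a stearoyl-CoA desaturase, of -1.49 ± 0.35 (adjusted p = 0.0223) and Cd63, a tetraspanin of late endosomes, of -1.40 ± 0.23 (adjusted p = 0.00545). H19 varied most, from 10.4 to 239 CPM in floxed tumours. H19 missed the threshold without Hmgb1-deleted tumours 2 and 5, without 3 and 4 and without 3, 4 and 6 (highest edgeR adjusted p = 0.0917), and Scd2 missed it without 2 and 5 (adjusted p = 0.0536).

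In the bile acid synthesis and transport list 8 of 16 members rose (10 adjusted over the list alone; camera adjusted p = 1.70e-06; adjusted p = 0.221 with an estimated correlation). Cyp7a1 rose by 2.99 ± 0.37 (SE) on the log2 scale, Baat, which conjugates bile acids, by 1.92 ± 0.29, Cyp27a1, a sterol hydroxylase, by 1.56 ± 0.28 and Akr1d1, a steroid reductase, by 1.52 ± 0.29, with adjusted p from 0.00131 to 0.00999. In the fatty acid oxidation and PPAR-alpha list 9 of 21 members rose (15 adjusted over the list alone; camera adjusted p = 3.64e-08; adjusted p = 0.324 with an estimated correlation). They included Cpt2, the inner carnitine palmitoyltransferase (1.07 ± 0.17, adjusted p = 0.0047), Acaa1b, a peroxisomal thiolase (2.28 ± 0.40, adjusted p = 0.00697), Acadm, a mitochondrial acyl-CoA dehydrogenase (0.74 ± 0.15, adjusted p = 0.0126), and Acot1, an acyl-CoA thioesterase (2.39 ± 0.49, adjusted p = 0.0131). Of the drug-metabolising cytochrome P450 list 6 of 16 members rose (10 adjusted over the list alone; camera adjusted p = 0.000537; adjusted p = 0.807 with an estimated correlation). Cyp2f2 rose by 3.03 ± 0.40 (SE), from 87.5 CPM ± 32.6 to 707 CPM ± 364, and Cyp2c50 by 3.20 ± 0.61. The lipogenesis and lipid storage list had 5 members higher and 1 lower of 20, the same counts adjusted over the list alone (camera adjusted p = 0.0222; adjusted p = 0.807 with an estimated correlation). Its leading members were the lipid droplet proteins Plin5 (1.59 ± 0.17, adjusted p = 0.000777) and Plin4 (2.95 ± 0.48, adjusted p = 0.00569). Hmgb1-deleted tumours 3, 4 and 6 lay nearest to normal liver. Without these 3 tumours, a choice made after seeing the data, the bile acid and fatty acid oxidation lists still passed, and the cytochrome P450 and lipogenesis lists did not (camera adjusted p = 0.511 and 0.456); without 3 and 4 alone the cytochrome P450 list was at 0.05396. With 3, 4 and 6 left out, Cyp2c50 and Acot1 had smaller log2 fold changes of 1.54 and 1.33 (edgeR adjusted p = 0.0625 and 0.123), and Acadm missed the threshold at a similar 0.70 with fewer samples (adjusted p = 0.0591). Of other hepatocyte lists, urea cycle and gluconeogenesis (median 0.47) and secreted proteins (median -0.26) did not pass over all 6 tumours (camera adjusted p = 0.374 and 0.184), and without the 3 tumours both were lower (adjusted p = 0.00215 and 0.00059). The removal of Hmgb1-deleted tumours 2 and 5, also chosen after seeing the data, turned the urea cycle list the other way, to higher (0.00317), and the secreted protein list also passed as lower without floxed tumour 5 (0.0405) or without 3 and 4 (0.0254). The lipogenesis list also missed the threshold when floxed tumour 4 or 5 or Hmgb1-deleted tumour 1 or 3 was left out (highest adjusted p = 0.0797) and with all 15 samples in 1 fit (0.0638).

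**Figure D3:**
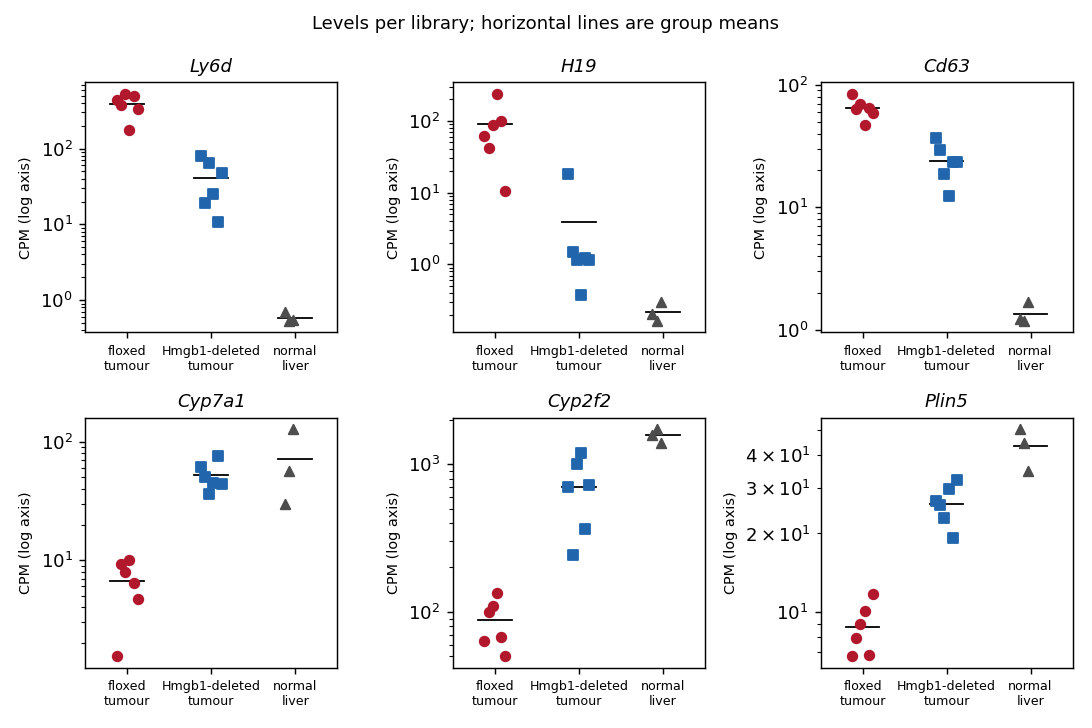
CPM per library on a log axis for Ly6d, H19, Cd63, Cyp7a1, Cyp2f2 and Plin5 in the 3 groups; points are libraries and horizontal lines are group means. Each Hmgb1-deleted tumour lies between floxed tumour and normal liver for Ly6d, and for Cyp7a1 the Hmgb1-deleted tumours (36.3 to 76.3 CPM) overlap the normal livers (30.0 to 128 CPM).

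Some liver genes that are higher in males rose too, and so did 2 zone-specific genes. In the male-biased list 4 of 15 members were higher (7 adjusted over the list alone; camera adjusted p = 0.00311; adjusted p = 0.807 with an estimated correlation). Cyp4a12a, a fatty acid hydroxylase, was at 528 CPM ± 339 (SD, n = 6) against 26.5 CPM ± 24.5. In the female-biased list 1 of 10 tested members was higher (1 higher and 1 lower adjusted over the list alone). That list did not pass (median -1.37, camera adjusted p = 0.164), but passed as lower without Hmgb1-deleted tumours 3, 4 and 6 (0.0263). The 5 largest rises with enough counts were Sult2a7 (6.17 ± 1.19), Mup17 (5.55 ± 0.84), Ugt2b38 (4.76 ± 1.11), Cyp4a12a (4.34 ± 0.79) and Mup1 (4.28 ± 1.06), given as log2 fold change ± SE, with adjusted p from 0.00451 to 0.0281. Ugt2b38 and Cyp4a12a are in the male-biased list, and Sult2a7, Mup17 and Mup1 are in none of the lists. All 5 belong to families of close copies, so their counts are uncertain, and Sult2a7 missed the threshold with voom (adjusted p = 0.121). Without Hmgb1-deleted tumours 3, 4 and 6, Sult2a7, Ugt2b38 and Mup1 had smaller log2 fold changes of 2.64, 2 and 2.38 and missed the threshold (edgeR adjusted p = 0.0581, 0.261 and 0.227). Sult2a7 was at 15.6 to 52.0 CPM in those 3 tumours and at 0.373 to 3.08 CPM in the other 3. Ugt2b38 missed the threshold without Hmgb1-deleted tumour 4 (adjusted p = 0.0538), and Mup1 missed it when any 1 of 7 libraries was left out, floxed 1, 2, 3, 5 or 6 or Hmgb1-deleted 3 or 4 (highest adjusted p = 0.0655). In the list of Wnt and beta-catenin targets, which mark hepatocytes around the central vein, 2 of 18 members rose (9 adjusted over the list alone; camera adjusted p = 0.00287; adjusted p = 0.807 with an estimated correlation). Rgn, a calcium-binding protein, rose by 2.18 ± 0.51 and missed the threshold without floxed tumour 2 or Hmgb1-deleted tumour 4 (highest adjusted p = 0.055). With Hmgb1-deleted tumours 3, 4 and 6 left out, Rgn had a smaller log2 fold change of 0.91 (edgeR adjusted p = 0.223). Without Hmgb1-deleted tumours 3, 4 and 6 neither the male-biased nor the Wnt list passed (camera adjusted p = 0.251 and 0.596).

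Targets of p53 and genes that report ERK signalling fell. In the p53 list 3 of 16 members were lower (12 adjusted over the list alone; camera adjusted p = 9.20e-07; adjusted p = 0.221 with an estimated correlation), led by the antiproliferative gene Btg2 at -1.39 ± 0.23 (adjusted p = 0.00545) and Zmat3, an RNA-binding protein, at -0.82 ± 0.17 (adjusted p = 0.0143). In the RAS, RAF and ERK feedback list 4 of 15 were lower (11 adjusted over the list alone; camera adjusted p = 9.20e-07; adjusted p = 0.146 with an estimated correlation): the transcription factors Etv4 (-2.63 ± 0.43), Egr1 (-1.51 ± 0.32) and Etv5 (-0.92 ± 0.21) and the feedback inhibitor Spry1 (-0.81 ± 0.14). Zmat3 and Spry1 missed the threshold on library totals without a factor (edgeR adjusted p = 0.146 and 0.103), and Zmat3 also without Hmgb1-deleted tumours 3, 4 and 6, at -0.68 (adjusted p = 0.0696). Smaller shifts passed for endothelial cell genes (median log2 fold change -0.38, 1 of 17 lower, Stab1), ER stress genes (-0.40, 1 of 14), cholangiocyte and progenitor genes (-0.43, 1 of 18, Prom1) and cholesterol synthesis genes (-0.15), of which 4 of 23 had an unadjusted edgeR p under 0.05, none passed after adjustment, and DESeq2 and voom called 1 each. Each of these 4 had an adjusted p of 0.807 with an estimated correlation. The endothelial list missed the threshold without floxed tumour 5 (0.0999) and the ER stress list without Hmgb1-deleted tumour 4 (0.0518). The cholangiocyte list did so without any 1 of floxed 2 to 5 or Hmgb1-deleted 3 to 6 (highest 0.159), and the cholesterol list without any 1 of floxed 2, 4 or 6 or Hmgb1-deleted 1, 2, 4 or 5 (highest 0.278). These last 2 lists also missed it with RLE factors (0.0679 and 0.0569) and with all 15 samples in 1 fit (0.0535 and 0.0638). The 5 largest falls were Tmem146 (-6.53 ± 1.06), Tmem54 (-5.37 ± 1.11), Cacna1b (-5.23 ± 0.74), Wfdc12 (-4.54 ± 0.84) and H19. With voom Tmem146 and Tmem54 missed the threshold (adjusted p = 0.0541 and 0.183). Tmem54 also missed it without Hmgb1-deleted tumours 3, 4 and 6, at a similar -5.69 with fewer samples (edgeR adjusted p = 0.0809). Cacna1b, a neuronal calcium channel subunit, was at 27.9 CPM ± 12.3 in floxed tumours and 0.748 CPM ± 0.839 in Hmgb1-deleted tumours. The lists of cell cycle genes (median 0.31, camera adjusted p = 0.593, and higher at 0.000138 without Hmgb1-deleted tumours 3 and 4 and at 6.47e-07 without 3, 4 and 6), HMGB1 receptors (-0.09, adjusted p = 0.825), extracellular matrix (-0.27, adjusted p = 0.707), macrophages (median 0.12, mean -0.14, 2 members lower, adjusted p = 0.449), lymphocytes (-0.25, adjusted p = 0.188) and neutrophils (-1.02, adjusted p = 0.1575) did not pass. Without floxed tumour 6 the lymphocyte and neutrophil lists passed as lower (0.0246 and 0.012), and the neutrophil list also did with all 15 samples in 1 fit (0.0155) and without Hmgb1-deleted tumours 3, 4 and 6 (0.0239). The extracellular matrix list passed as higher without floxed tumour 5 (0.0305). The cytokine and chemokine list had 3 of 22 members lower and did not pass (median -0.07, camera adjusted p = 0.333). The glycolysis list, with 1 higher and 1 lower of 16, missed the threshold narrowly (median -0.42, camera adjusted p = 0.0502). It passed as lower with the replicate block (0.0193) and without any 1 of floxed 1, 2, 4 or 6 (highest 0.0342). In all, 13 of 32 tested lists passed with camera's preset correlation, 1 with an estimated correlation (fetal and oncofetal liver) and 5 with fry. The number of changed genes was 589 without Hmgb1-deleted tumour 4, 422 without Hmgb1-deleted tumours 3 and 4, 808 (344 higher and 464 lower) without 3, 4 and 6, 1629 with all 15 samples in 1 fit and 1954 with DESeq2.

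Floxed tumours were then set against normal liver to show what tumours with intact Hmgb1 look like. The fetal liver, cell cycle and cytokine lists were higher in them, and the bile acid, urea cycle and cytochrome P450 lists were lower. The fetal list kept its call with an estimated correlation, and the others, in this order, lost it (adjusted p = 0.3995, 0.266, 0.0771, 0.266 and 0.147 with an estimated correlation). Afp, the fetal serum protein used as a liver tumour marker, was at 183 CPM ± 45.2 (SD, n = 6) against 2.72 CPM ± 1.06 (SD, n = 3), and Ly6d at 389 CPM ± 126 against 0.587 CPM ± 0.0897. Cps1, the entry enzyme of the urea cycle, was at 454 CPM ± 125 against 3811 CPM ± 388. In all, 6714 of 13784 genes changed, 3437 higher and 3277 lower, and 3944 by at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). Upper-quartile scaling, which shifted the median of all genes by 0.18, gave 4363 higher and 2509 lower.

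In the fetal and oncofetal list 14 of 17 members rose (15 adjusted over the list alone; camera adjusted p = 5.91e-09; adjusted p = 0.0147 with an estimated correlation). The log2 fold changes were 10.87 ± 0.55 (SE) for Akr1c18, a steroid-metabolising reductase, 9.36 ± 0.48 for Ly6d, 6.08 ± 0.37 for Afp and 5.58 ± 0.24 for Cd63. Of 30 cell cycle genes 25 rose, also adjusted over the list alone (camera adjusted p = 5.67e-08; adjusted p = 0.3995 with an estimated correlation). Mki67, the Ki-67 proliferation marker, rose by 3.60 ± 0.52, the transcription factor Foxm1 by 2.99 ± 0.36 and cyclin A2 (Ccna2) by 3.50 ± 0.45. In the p53 list 11 of 16 members were higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 7.26e-05; adjusted p = 0.147 with an estimated correlation), with Phlda3, an inhibitor of AKT, up by 5.48 ± 0.48. Of 24 macrophage and Kupffer cell genes 15 rose (15 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000369; adjusted p = 0.374 with an estimated correlation), with Mpeg1 at 368 CPM ± 46.4 against 65.4 CPM ± 2.87. Of 22 cytokine and chemokine genes 19 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 9.45e-06; adjusted p = 0.266 with an estimated correlation), among them Lif (6.81 ± 0.49), a cytokine of the IL-6 family.

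In the bile acid list 15 of 16 members fell (15 adjusted over the list alone; camera adjusted p = 3.54e-09; adjusted p = 0.0771 with an estimated correlation). Cyp8b1, which sets the share of cholic acid, had a log2 fold change of -5.49 ± 0.31, the uptake transporter Slco1b2 of -4.27 ± 0.37 and Hsd3b7 of -2.66 ± 0.16. Of 16 cytochrome P450 genes 14 fell (14 adjusted over the list alone; camera adjusted p = 6.67e-07; adjusted p = 0.147 with an estimated correlation), with Cyp2c29 at 75.9 CPM ± 25.7 against 2256 CPM ± 482. Of 15 urea cycle and gluconeogenesis genes 14 fell (14 adjusted over the list alone; camera adjusted p = 2.32e-06; adjusted p = 0.266 with an estimated correlation), and of 21 fatty acid oxidation genes 18 fell and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 1.43e-07; adjusted p = 0.266 with an estimated correlation). Cpt2 was at 54.9 CPM ± 8.61 against 219 CPM ± 23.2, and Acaa1b at 163 CPM ± 40.3 against 1104 CPM ± 169. Of 18 Wnt and beta-catenin targets 14 fell (15 adjusted over the list alone; camera adjusted p = 3.01e-06; adjusted p = 0.309 with an estimated correlation), including Cyp2e1 (-4.03 ± 0.51) and Cyp1a2 (-3.43 ± 0.37). In the male-biased list 14 of 15 members fell (14 adjusted over the list alone; camera adjusted p = 1.43e-07; adjusted p = 0.266 with an estimated correlation). Mup7, a major urinary protein, was at 0.811 CPM ± 1.07 against 1108 CPM ± 232. In the female-biased list 8 of 10 members were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0263; adjusted p = 0.465 with an estimated correlation), led by Cyp2a4 (9.31 ± 1.35).

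The largest rises were in genes nearly silent in normal liver. Csn3, a milk casein, and Cacna1b had 0 counts in all 3 normal livers and were at least 891-fold and 621-fold higher in floxed tumours, against a floor of 3 counts over the group; without floxed tumour 1, at 112.8 CPM, the bound for Csn3 was 576-fold. Slc7a11, the cystine transporter, and H2-Ea-ps, an MHC class II sequence, each had 1 count over the 3 normal livers, which gives ratios of 3455 (95% counting interval 620 to 136470) and 3449 (619 to 136238). H2-Ea-ps was also near 0 in Hmgb1-deleted tumours 3 and 4, at 0.0531 and 0.108 CPM. The strain of the tumour mice is not given, so for this gene a strain difference cannot be told apart from a rise with tumour. Akr1c18 completed the 5 largest rises. The 5 largest falls were Mup7, Pitx3, Mup1, Mup15 and Mup17. Pitx3, a homeobox factor, had 0 counts in floxed tumours and was at least 309.6-fold lower, from 6.76 CPM ± 7.15 in normal liver. Without normal liver 1, at 14.7 CPM against 4.89 and 0.739 CPM in the other 2, that bound was 130.5-fold. The Mup genes are close copies of each other and their counts are uncertain. In all, 22 of 33 lists passed with camera, 1 with an estimated correlation (fetal and oncofetal liver) and 21 with fry.

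**Figure D4:**
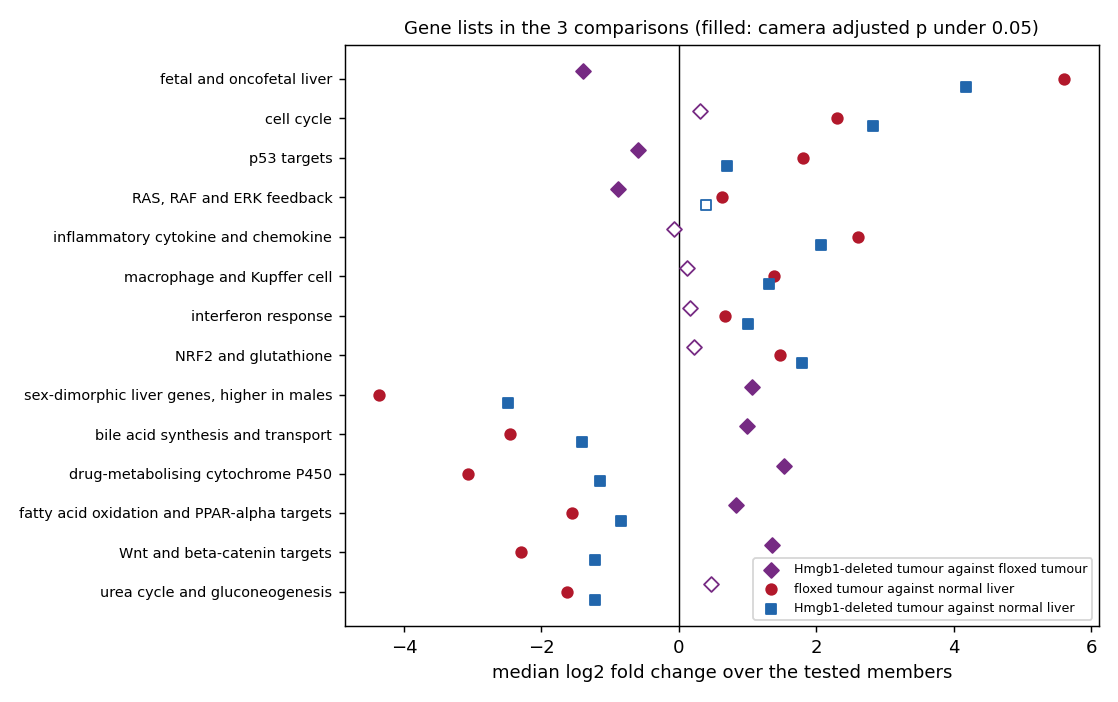
Median log2 fold change over the tested members (x axis) of 14 gene lists (y axis) in the 3 comparisons; markers and colours show the comparison, and filled markers have a camera adjusted p under 0.05 with the preset correlation. The fetal and oncofetal list has medians of 5.61, 4.18 and -1.40, and the bile acid list of -2.46, -1.41 and 0.99, for floxed tumour against normal liver, Hmgb1-deleted tumour against normal liver and Hmgb1-deleted against floxed tumour.

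Hmgb1-deleted tumours were set against the same normal livers. The fetal, cell cycle, cytokine and NRF2 lists were higher in them too, and the bile acid list was lower. The fetal list kept its call with an estimated correlation, and the others, in this order, lost it (adjusted p = 0.48, 0.241, 0.241 and 0.241 with an estimated correlation). Cd63 was at 24.0 CPM ± 8.37 (SD, n = 6) against 1.36 CPM ± 0.274 (SD, n = 3), and Mki67 at 35.6 CPM ± 25.8 against 2.43 CPM ± 0.108. Slco1a1, a bile acid and steroid uptake transporter, was at 19.4 CPM ± 7.67 against 677 CPM ± 75.2. In all, 4787 of 13784 genes changed, 2492 higher and 2295 lower, and 2476 by at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). The split was 3390 higher and 1578 lower with upper-quartile scaling, and 2969 and 1062 on library totals without a factor; these scalings shifted the median of all genes by 0.15 and 0.28.

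Of 18 fetal and oncofetal genes 13 rose, also adjusted over the list alone (camera adjusted p = 2.34e-06; adjusted p = 0.0303 with an estimated correlation). The log2 fold changes were 7.25 ± 0.53 (SE) for Cbr3, a carbonyl reductase, 4.17 ± 0.39 for Cd63, 4.11 ± 0.53 for Scd2 and 3.77 ± 0.42 for Golm1, a Golgi membrane protein. Of 30 cell cycle genes 22 rose (27 adjusted over the list alone; camera adjusted p = 2.04e-08; adjusted p = 0.48 with an estimated correlation), with Ccna2 up by 3.90 ± 0.70 and Ube2c, an anaphase enzyme, by 4.91 ± 0.97. Of 20 NRF2 and glutathione genes 15 rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 2.33e-06; adjusted p = 0.241 with an estimated correlation). Gstm1, a glutathione transferase, was at 2914 CPM ± 491 against 764 CPM ± 141, and the efflux pump Abcc4 at 73.0 CPM ± 22.8 against 3.21 CPM ± 0.4659. Of 22 interferon response genes 13 rose (13 adjusted over the list alone; camera adjusted p = 1.35e-05; adjusted p = 0.0747 with an estimated correlation), with Oas1a up by 2.26 ± 0.26 and Isg15 by 1.41 ± 0.20. Of 22 cytokine and chemokine genes 19 rose (19 adjusted over the list alone; camera adjusted p = 2.33e-06; adjusted p = 0.241 with an estimated correlation), including Vcam1 (2.13 ± 0.32), an adhesion molecule. Of 24 macrophage and Kupffer cell genes 16 rose (16 adjusted over the list alone; camera adjusted p = 8.63e-05; adjusted p = 0.241 with an estimated correlation), among them Gpnmb (3.73 ± 0.40) and Trem2 (3.44 ± 0.62), both expressed by lipid-handling macrophages.

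Among lowered groups, 10 of 15 male-biased genes fell (12 adjusted over the list alone; camera adjusted p = 2.33e-06; adjusted p = 0.241 with an estimated correlation), including Slco1a1 (-5.11 ± 0.32) and Cyp7b1 (-3.44 ± 0.44), an oxysterol hydroxylase. In the bile acid list 8 of 16 fell (9 adjusted over the list alone; camera adjusted p = 9.42e-06; adjusted p = 0.241 with an estimated correlation), and Cyp8b1 was at 38.1 CPM ± 30.6 against 558 CPM ± 158. The largest rises were Sult1e1 and Sprr1a, with 0 counts in the normal livers and at least 232-fold and 252-fold higher, and H2-Ea-ps, Slc7a11 and Spink3. The bound for Sprr1a was 40.3-fold without Hmgb1-deleted tumour 1, at 49.4 CPM against 0.41 to 4.04 CPM in the other 5, and that for Sult1e1 151-fold without Hmgb1-deleted tumour 4. H2-Ea-ps was at 0.0531 and 0.108 CPM in Hmgb1-deleted tumours 3 and 4 and at 25.7 to 87.1 CPM in the other 4. Here too a strain difference cannot be told apart from a rise with tumour for this gene. The largest falls were Mup7 (-9.83 ± 0.74), Hsd3b5 (-7.56 ± 0.74), Susd4 (-6.79 ± 0.38), Rfx4 (-6.68 ± 0.74) and Mup15 (-6.18 ± 0.78). Sult1e1, Sprr1a and H2-Ea-ps missed the threshold without normal liver 1 or 2, Sprr1a and H2-Ea-ps also without normal liver 3, and Sprr1a also without Hmgb1-deleted tumour 2 or 4 (highest edgeR adjusted p = 0.0596 for Sult1e1, 0.109 for Sprr1a and 0.094 for H2-Ea-ps). In all, 20 of 32 lists passed with camera, 1 with an estimated correlation (fetal and oncofetal liver) and 17 with fry. The number of changed genes was 2113, 2227 and 3109 without normal liver 1, 2 and 3, so the count depends on each of the 3 normal livers.

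The changes against normal liver overlapped between the tumour groups. Of 13563 genes tested in both comparisons, 2086 were higher in both, 1937 lower in both and 4 went opposite ways. Independent lists of these sizes would share 594 higher and 553 lower genes. The log2 fold changes correlated across genes with r = 0.90, against 0.68 for simulated unchanged groups, and genes are not independent replicates. Their covariance was 1.63 against 0.10 in the simulation. The 3 normal livers are too few to be split, so part of the overlap may come from the shared controls.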

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

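The tests of the H2 locus, of mixed-in liver, of female animals and of paralogs were chosen after the results were seen, the first 2 were each replaced once after their outcome was seen, and both versions are given. The splits of the samples and the test of MHC class II cells were planned.

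Splits of the same samples were used to see whether chance can be excluded. For the number of genes, chance is argued against in each comparison, since no other split reached the real count. This holds only if the samples are independent, which the labels do not say. For Hmgb1-deleted against floxed tumours, 1 of 100 splits drawn from 462, the real one, gave as many as the 1045 genes, and the highest other gave 3. For floxed tumours against normal liver it was 1 of 84 splits, with 6714 genes against 2. For Hmgb1-deleted tumours against normal liver it was 1 of 84, with 4787 against 3389, from the split that puts Hmgb1-deleted tumours 3, 4 and 6 with the normal livers, so the samples hold a structure of their own. For gene lists chance is not excluded: 54 of 100 splits gave as many as 13 lists (highest other 21), 11 of 84 as many as 22 (24) and 11 of 84 as many as 20 (24). Among single lists in Hmgb1-deleted against floxed tumours, a camera p as small came in 1 of 100 splits for the fetal and oncofetal list, in 2 of 100 for RAS, RAF and ERK feedback, and in 3 of 100 for bile acid, fatty acid oxidation and p53. It came in 18 of 100 for cytochrome P450, 19 for male-biased genes, 22 for Wnt targets, 25 for lipogenesis, 27 for endothelial cells, 27 for ER stress, 36 for cholangiocytes and 60 for cholesterol synthesis, so chance is not excluded for these 8. The counts were not adjusted over the lists, so the low ones do not exclude chance for a single list either.

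H2-Ea-ps, an MHC class II sequence, was near 0 in Hmgb1-deleted tumours 3 and 4 and in the normal livers and at 25.7 to 87.1 CPM in the other 10 tumours. A lack of MHC class II cells in those 2 tumours is argued against by H2-Aa, H2-Ab1, H2-Eb1 and Cd74, whose geometric mean was at 0.645 and 1.296 times the median of the other 10. A strain variant at the H2 locus was first tested with H2-Ea-ps itself counted, and 2 of the 4 genes with this split lay near it (Fisher p = 0.000788), but that counts the gene the pattern was found in. Without it 1 of 3 genes did, H2-Q2 (Fisher p = 0.0341). Gm11127 and Vmn2r3 did not lie within the 150 genes on either side of H2-Ea-ps that were counted as near. That limit does not mark the ends of the H2 locus, so the test cannot decide, and a strain variant stays open. No other biological explanation was tested.

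Hmgb1-deleted tumours 3, 4 and 6 lay nearest to normal liver on the first principal component. Untreated normal liver mixed into these libraries was tested first on 67 genes at least 16 times lower in floxed tumour, whose median level was 21.9%, 32.3% and 22.0% of normal, over 0.5 of the share the component implies (41.9%, 45.5% and 34.3%), as a mixture would give. The test was then replaced, with genes picked knowing their levels, since a mixture brings every abundant transcript: Mup7, at 1108 CPM in normal liver, was at 0.0959%, 0.121% and 0.244% of that level, Hsd3b5 at 0.475% to 1.28%, and the highest of these and Slco1a1 was 4.24%. Over all 67 genes, 19 were under 0.5 of the implied share in all 3 libraries. These values argue against a mixture with liver like these normal livers as the whole cause, although the first test went with a mixture. The strain of the tumour mice is not known, so liver with other levels of these genes is not excluded. Nor is a share too small to give the pattern. Treated liver around the tumour may also lie behind the pattern, with 0 samples of such liver to test it, and an effect of the deletion itself stays open and untested. A strain difference among the tumours stays open and untested too. Tumours 3 and 4 shared the near-0 H2-Ea-ps level of the C57BL/6 normal livers, while tumour 6, at 25.7 CPM, did not.

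Male-biased liver genes were lower in both tumour groups than in normal liver. Female animals among the tumours are argued against by Ddx3y, a Y-linked gene, at 55.066 CPM or more in each tumour, and by Xist at 0.348 CPM or less. Reads shared between near-identical paralogs are argued against as the whole cause by the 6 members outside the copied families, with median log2 fold changes of -4.37 in floxed and -3.3182 in Hmgb1-deleted tumours. The treatment and being a tumour stay open, as untested.

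Of 213 groups of values, 13 held a library far from the others of its group, against 10.6 expected by chance, and 4 of these were in floxed tumour 5. The numbers given are the gap to the nearest library as a share of the group's range, on the scale of log2(CPM + 1) for genes and of the count itself for the total count. In floxed tumour 5, Col1a1 was highest (0.737; 427 CPM against 19.6 to 44.8), Tlr4 was highest (0.673), and Ube2c (0.754) and Mki67 (0.638) were lowest. In Hmgb1-deleted tumour 1, Hmgb1 was lowest (0.702; 9.59 CPM against 14.8 to 17.8), and H19 (0.776) and Sprr1a (0.644) were highest. Egr1 was highest in Hmgb1-deleted tumour 3 (0.709) and Pitx3 in Hmgb1-deleted tumour 6 (0.896). Cyp2c29 was lowest in floxed tumour 1 (0.725), Abcc4 lowest in floxed tumour 3 (0.664), Mup1 highest in floxed tumour 4 (0.633) and the total count highest in floxed tumour 6 (0.813).

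Against normal liver 4 genes were called in opposite directions in the tumour groups. They were picked for that difference, so their fold changes between the tumour groups are no independent support for it. Cpm (-2.792), Tmem146 (-6.528) and Zap70 (-3.969) were higher in floxed and lower in Hmgb1-deleted tumours than in normal liver, and Omd (3.892) the reverse, given as log2 fold changes of Hmgb1-deleted against floxed tumours.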

How the results depend on the processing

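Library totals for the gene counts, the removal of Hmgb1-deleted tumours 2 and 5, of 3 and 4 and of 3, 4 and 6, and numbers 1 to 3 without a block were chosen after seeing the data. For Hmgb1-deleted against floxed tumours, 1045 genes became 1954 with DESeq2, whose false calls in simulation were 16%, 1629 with all 15 samples in 1 fit, 422 without Hmgb1-deleted tumours 3 and 4, and 589 to 1054 with each library left out. The removal of 3, 4 and 6 was run, then set aside for 3 and 4 because it selects libraries by their outcome, and is restored here: it gave 808 genes and 15 lists, turned the urea cycle list to lower (adjusted p = 0.002152), which without 2 and 5 passed as higher (0.003169), and moved the cholangiocyte list to the other side at no significance (0.8708). The extracellular matrix list reversed without floxed tumour 5, at adjusted p = 0.03046, and ranged up to 0.944 over left-out libraries. With an estimated correlation 1 list passed in each comparison, and with fry 5 did for Hmgb1-deleted against floxed tumours. For Hmgb1-deleted tumours against normal liver, 4787 genes became 3055 with numbers 1 to 3 and a replicate block (3679 without the block) and 2113 to 4912 with each library left out. The block gave 860 and 6579 genes in the other comparisons. Nothing in the labels says that the numbers pair the samples. Correlations passed 0.1 in 2 of 6 pairs for Hmgb1-deleted against floxed tumours, and in 1 of 3 for floxed and for Hmgb1-deleted tumours against normal liver. The own number was the best partner in 1 of 6, 2 of 3 and 1 of 3. So few pairs cannot decide whether the numbers pair the samples. The Hmgb1 difference against normal liver was -0.384266 on library totals and -0.793442 to -0.465389 with each library left out, no longer past the threshold when a normal liver was, where fewer samples fix the smallest p at 0.0714. The shared calls fell from 4023 to 1500 at an adjusted p under 0.01. Single genes lost their call in 174, 12 and 62 of the runs over all settings for Hmgb1-deleted against floxed tumours, floxed tumours against normal liver and Hmgb1-deleted tumours against normal liver, and gained one in 68, 1 and none. Single lists lost it in 58, 33 and 37 and gained it in 21, 11 and 21. Except where a cause is given, the cause was not tested. Depth limits genes under about 0.169 CPM in a library.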

Other observations

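The lists here were fixed before the data were seen. Chosen afterwards were the removals of 2 or 3 Hmgb1-deleted tumours and the fits of shared replicate numbers without a block, all named below. No other test of this part was chosen afterwards.

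Further lists passed camera's preset test against normal liver in both tumour groups. Values are given for floxed and then for Hmgb1-deleted tumours. HMGB1 receptors rose in 6 and 6 of 7 members (6 and 6 adjusted over the list alone; camera adjusted p = 0.00915 and 0.00173; adjusted p = 0.374 and 0.4435 with an estimated correlation). ER stress genes rose in 9 and 8 of 14 (10 and 8 adjusted over the list alone; camera adjusted p = 0.000733 and 0.00218; adjusted p = 0.374 and 0.48 with an estimated correlation). Cholangiocyte and progenitor genes rose in 11 and 7 of 19 (12 and 7 adjusted over the list alone; camera adjusted p = 0.00166 and 0.0176; adjusted p = 0.395 and 0.536 with an estimated correlation), among them the stem cell marker Prom1 (log2 fold change ± SE, 5.12 ± 0.54 and 3.05 ± 0.47). Lymphocyte genes rose in 8 and 10 of 21, with 1 lower in Hmgb1-deleted tumours (8, and 12 with 1 lower, adjusted over the list alone; camera adjusted p = 0.0226 and 0.00482; adjusted p = 0.618 and 0.241 with an estimated correlation). In the Notch list, which holds receptors and ligands as well as targets, 7 and 5 of 11 members rose. Adjusted over the list alone it was 7, and 6 with 1 lower. The camera adjusted p was 0.0441 and 0.0485, and with an estimated correlation it was 0.613 and 0.511. Extracellular matrix genes rose in 9 and 8 of 30, with 1 lower in Hmgb1-deleted tumours (8, and 4 with 1 lower, adjusted over the list alone; camera adjusted p = 0.0396 and 0.00559; adjusted p = 0.736 and 0.589 with an estimated correlation).

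In floxed tumours against normal liver, neutrophil genes rose in 6 of 7 (6 adjusted over the list alone; camera adjusted p = 0.0218; adjusted p = 0.533 with an estimated correlation) and RAS, RAF and ERK feedback genes in 7 of 15 with 1 lower (the same adjusted over the list alone; camera adjusted p = 0.0127; adjusted p = 0.465 with an estimated correlation). Interferon genes rose in 8 of 22 (8 adjusted over the list alone; camera adjusted p = 0.0088; adjusted p = 0.5681 with an estimated correlation) and NRF2 genes in 11 of 20 with 3 lower (the same adjusted over the list alone; camera adjusted p = 0.00915; adjusted p = 0.5681 with an estimated correlation). In Hmgb1-deleted tumours against normal liver, p53 targets rose in 7 of 16 with 1 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.014; adjusted p = 0.511 with an estimated correlation). There 4 of 16 cytochrome P450 genes fell (4 adjusted over the list alone) and 7 of 18 Wnt targets (7 adjusted over the list alone), each at camera adjusted p = 0.000534 and adjusted p = 0.511 with an estimated correlation. Urea cycle genes fell in 5 of 15 (5 adjusted over the list alone; camera adjusted p = 8.63e-05; adjusted p = 0.48 with an estimated correlation) and fatty acid oxidation genes in 8 of 21 with 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.000186; adjusted p = 0.48 with an estimated correlation). Cholesterol genes fell in 6 of 23 (5 adjusted over the list alone; camera adjusted p = 0.0234; adjusted p = 0.683 with an estimated correlation).

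Some of these list calls ended when 1 library was left out, given here with the highest camera adjusted p. In floxed tumours these were extracellular matrix (floxed 5, normal 1 or 3; 0.0709), lymphocyte (floxed 1; 0.0742), neutrophil (floxed 5; 0.05998) and Notch (normal 2 or 3; 0.0673). In Hmgb1-deleted tumours they were cholangiocyte (Hmgb1-deleted 1; 0.0527), p53 (normal 3; 0.0616), Notch (Hmgb1-deleted 1 or 2, normal 3; 0.0792) and cholesterol (Hmgb1-deleted 1 or 5, normal 3; 0.192). The extracellular matrix call in floxed tumours also ended on numbers 1 to 3, with a replicate block (0.07175) or without (0.0841), and the Notch call there without the block (0.0505). In Hmgb1-deleted tumours the Notch call also ended with all 15 samples in 1 fit (0.0862) and without tumours 2 and 5 (0.0856), and the cholesterol call on numbers 1 to 3 without the block (0.0779) and without tumours 2 and 5 (0.139). The lymphocyte call there ended without tumours 3, 4 and 6 (0.0607).

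Other splits of the 9 samples gave a camera p as small for most of these lists in so many cases that chance is not excluded. For floxed tumours, out of 84 splits with the real one included, the number was 10 for HMGB1 receptors, 13 for ER stress, 20 for cholangiocytes, 43 for lymphocytes, 44 for Notch, 65 for extracellular matrix, 30 for neutrophils, 23 for RAS, RAF and ERK feedback, 30 for interferon and 28 for NRF2. For Hmgb1-deleted tumours it was 25 for ER stress, 43 for cholangiocytes, 11 for lymphocytes, 31 for Notch, 37 for extracellular matrix, 15 for p53, 32 for cytochrome P450, 27 for Wnt, 25 for urea cycle, 16 for fatty acid oxidation and 47 for cholesterol. The number was lowest for HMGB1 receptors in Hmgb1-deleted tumours, at 3 of 84. Of lists given in the report, it was 1 of 84 in floxed tumours for fetal liver, bile acid, cytochrome P450 and p53, 2 for fatty acid oxidation, 6 for male-biased genes, 7 for urea cycle and for cytokines, 8 for Wnt, 11 for cell cycle, 15 for macrophages and 25 for female-biased genes. In Hmgb1-deleted tumours it was 2 for male-biased genes and for cytokines, 3 for fetal liver and NRF2, 4 for bile acid and interferon, 5 for macrophages and 12 for cell cycle. These numbers were not adjusted over the lists, so even a number of 4 or lower does not exclude chance for a single list.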
